A study of Caenorhabditis elegans with 2 samples.

How the data were processed

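Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was performed on whole *Caenorhabditis elegans* at the L2 larval stage, with both sexes mixed. The animals carried an integrated transgene that expresses the zinc finger protein ZTF-4 fused to enhanced green fluorescent protein, together with an unc-119 rescue marker in an unc-119 mutant background. Per the labels, the series holds 2 biological replicates of 1 group, with a library size range of 150 to 350 bp and a control listed. The control itself was not used here, and whether it came from the transgenic strain is not given in the sources used here.

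The authors deposited lists of regions in narrowPeak format on the builds ce10 and ce11. For each build there was a list per replicate, a list from the pooled replicates, and a list of peaks past a threshold of the irreproducible discovery rate (IDR), a measure of how well ranks agree between replicates. Per the listing of which file was derived from which, the lists given to IDR were made from each replicate's alignments, or from both pooled, and a control. The aligner, the peak caller, their versions and the IDR threshold are not given in the sources used here. The signal value of each region is the authors' own, in the deposited seventh column, and how it was scaled is not given, so it was used only to describe and rank regions within a list. The deposited ninth column was read as −log10 of the q-value, from the column order of the format. Each list given to IDR held exactly 30000 regions in the deposited files, most of them background. The files hold no read counts, so the depth of each library is unknown and no interval here covers counting of reads.

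All positions are on ce11, the same assembly as the reference used for annotation (WBcel235), and every last region end lay within the reference chromosome. The ce10 lists were compared by counts and values only, and no coordinates were converted. Genes and transcript start sites came from Ensembl release 115, and sequences came from the RefSeq copy of the genome. Summits were taken from the deposited summit offsets. A region was near a gene when its summit lay within 500 bp of any annotated start site of that gene, so a peak between neighbouring genes counted for each. Annotated start sites in this species can be trans-splice sites rather than sites of initiation.

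Peaks were compared with background regions, defined as the 15000 regions of lowest signal in the pooled list less those that overlapped a peak, which left 14862. Shares were compared by two-sided Fisher's exact tests with Benjamini-Hochberg adjustment within each family (7 annotation classes, 6 chromosomes, 31 gene lists, and all sequence words). Odds ratios carry 95% intervals from the log odds, with 0.5 added to each cell where one was 0, and shares carry 95% Wilson intervals. Annotation classes were assigned by the summit in a fixed order, with promoter (within 500 bp of a protein-coding start site) first. Of the gene lists, 27 were defined by gene symbol and tested among protein-coding genes with any region of the pooled list near them. The other 4 were defined by biotype and tested among all such genes. Sequence words of 6 bases, each joined with its reverse complement, were scored as present or absent within 50 bp of the summit. Words were found on chromosomes I, III and V and retested on II, IV and X. Overlap meant at least 1 bp. Signal values of the replicates were correlated across peaks with two-sided permutation tests of 100000 resamples. Neighbouring regions and genes that share a peak are not independent, so p-values across them are too small to an unknown degree.

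The comparisons, gene lists, alternatives and the rule for named genes were fixed before the data were examined, except those given as chosen later. The rule took the 25 protein-coding genes whose start site was nearest to, and within 1000 bp of, the highest peaks by pooled signal that overlapped a top region of both replicates. It added ztf-4, unc-119 and the 4 members with the highest peak from each gene list past an adjusted p of 0.05. Alternatives were each replicate's own top-ranked regions as peaks, the 897 peaks of highest signal, peaks in the top of both replicates, reciprocal overlap, other numbers of top regions, windows of 250 and 1000 bp, a flank of 100 bp, background from the regions ranked directly below the peaks, GC-matched background for the words, all annotated genes as the reference set, and the ce10 lists. Chosen after seeing the data were the comparisons of position relative to the start site and of start sites of several genes, the further RNA gene groups, the tests on peaks far from start sites, GC-matched background for start sites, biotype lists without piRNA genes, biotype lists with only regions over 500 bp from protein-coding start sites, peaks within 1000 bp of each other counted once, and the test of GC content near ribosomal protein genes in both its windows. GC matching paired peaks with background regions in bins of 2 percentage points.

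Analyses used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. The list and word tests were tested on simulated data. For the gene list comparison, over 6779 genes, a planted list of 20 genes with an odds ratio of 4 was called in 41 of 100 draws, against 77 for lists of 40 genes and 97 for lists of 70. A planted list of 20 genes with an odds ratio of 12 was called in 97 of 100 draws, and with an odds ratio of 1 in 0. Peaks were drawn for each gene independently, so these draws do not cover genes that share a peak. The lists defined by biotype were not simulated. For the word comparison, over 1794 windows, 0 words were called when none was planted. Both sets were random draws from the regions of lowest signal, so they did not differ in GC content as peaks and background did (44.96% against 32.6%). The simulation does not cover that difference. A single word planted in 5% of windows was found as 1 word, but planted in 10% it gave 6 called words and in 20% it gave 13, so counts of words exceed the number of distinct sequences. The 2 deposited text listings of file derivation hold no measurements and were read only for how files were made.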

Results

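ChIP-seq of green fluorescent protein-tagged ZTF-4, a zinc finger protein, was carried out in L2 larvae of *C. elegans* in 2 biological replicates of a single group. The question put to the data was where in the genome the tagged protein was recovered and how far the replicates gave the same regions. The IDR-thresholded list held 1794 peaks on ce11 (1789 distinct regions) and 1781 on ce10. Library depth is unknown, because the region lists hold no read counts.

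The highest peak lay 283 bp upstream of the start site of rpl-3 (III:3867854-3869587), which encodes a protein of the large ribosomal subunit, at III:3867426-3867711. It had a pooled signal value of 843 and ranked first in the pooled list and in both replicates. The next peaks lay upstream of cdc-48.1 (signal 688), which encodes an AAA ATPase, between Y17G9B.5 and the ribosomal protein gene rpl-20 (630), and upstream of ufbp-1 (613), rpl-15 (596), tasp-1 (572) and rpl-35 (553). Each of these 7 peaks ranked among the first 7 of both replicates. Further genes within 500 bp of the highest peaks were rps-1 (378), cox-5A (377), which encodes a subunit of cytochrome c oxidase, puf-9 (341), wwp-1 (333), iff-2 (330) and rpl-12 (324). Also within 500 bp were mstr-1, rpn-3, his-37, hsr-9 and F36A2.7, with signals from 314 down to 285. The other genes named by the same rule had their start sites farther from the summit, at 558 bp for tag-340 (365), 919 bp for cbp-1 (349), 729 bp for nspc-17 (322), 723 bp for ikke-1 (310) and 745 bp for mdt-26 (295). The peaks nearest to egg-5 (signal 399) and ZK1248.17 (383) among protein-coding genes lay 594 and 715 bp from their start sites, and 23 and 39 bp from those of the spliced leader RNA genes sls-2.4 and sls-2.1. These signal values are the authors' own and ranked peaks within a list.

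Peak signals over the whole list ran from 60.2 to 843 with a median of 83.0. The 1794 peaks were exactly the regions of highest signal in the pooled list, and the next region below had a signal of 60.1. Of the peaks, 91.8% had a width of 364 bp. Nearly every peak overlapped a region of replicate 1 (1788 peaks) and of replicate 2 (1793 peaks), each of which listed 30000 regions.

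Replicates shared most of their top-ranked regions. Of the 1794 highest regions of replicate 1, 1148 overlapped one of the 1794 highest of replicate 2. Among the 16097 regions of replicate 1 that overlapped any region of replicate 2, 12.9% overlapped a top region of it, and the odds ratio for a top region was 27.3 (95% interval 24.2 to 30.7; Fisher's exact p below what double precision holds). Of the peaks, 1138 (63.4%) overlapped a top region of both replicates and 66 (3.68%) a top region of neither. Across 1787 peaks matched in both replicates, signal values correlated with a Spearman's rho of 0.524 and a Pearson's r of 0.834 (permutation p = 1e-05 for each, the smallest the permutations can give). These correlations are across peaks selected on their pooled signal, and peaks are not independent replicates.

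**Figure D1:**
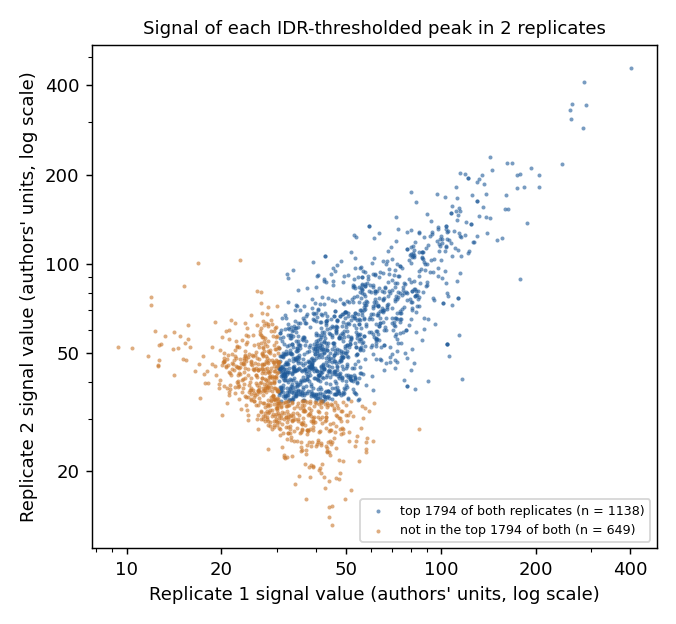
Signal value of each peak in replicate 1 (horizontal, authors' units, log scale) and replicate 2 (vertical, authors' units, log scale), for the 1787 peaks matched in both. Blue points are the 1138 peaks within the 1794 highest regions of both replicates, orange points are the others, and the point at the upper right is the peak upstream of rpl-3.

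Peaks lay near protein-coding start sites more often than background regions did. Of the 1794 peaks, 864 (48.2%, Wilson interval 45.9 to 50.5%) had their summit within 500 bp of a start site, against 3525 of 14862 background regions (23.7%), an odds ratio of 2.99 (2.70 to 3.30; Fisher's exact p = 2.39e-98). Of each replicate's own 1794 highest regions, 826 in replicate 1 and 871 in replicate 2 lay near a start site. Of the 864 peaks, 87.2% lay upstream of the nearest start site, against 54.8% of background regions near one (odds ratio 5.61, 4.54 to 6.92; Fisher's exact p = 2.58e-77), with a median position of -168.5 bp against -42 bp. Start sites of at least 2 genes lay within 500 bp of 23.4% of these peaks and 4.96% of such background regions (odds ratio 5.84, 4.69 to 7.27; Fisher's exact p = 5.37e-54), as at Y17G9B.5 and rpl-20 or at rpn-3 and the chaperone gene hsp-110. The position and shared-promoter comparisons were chosen after the peaks were seen. With the regions ranked directly below the peaks as background, 38.2% lay near a start site and the odds ratio was 1.501 (1.31 to 1.71).

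Coding exons held 1.90% of peaks and 8.70% of background regions (odds ratio 0.203, exact adjusted p = 4.02e-31), introns 15.8% and 30.4% (0.429, adjusted p = 2.53e-41) and 3' UTRs 1.95% and 4.21% (0.452, adjusted p = 9.64e-07). Exons of noncoding genes held 3.23% of peaks and 1.20% of background (2.74, exact adjusted p = 3.49e-09). Intergenic sequence held 28.7% and 31.5% (0.876, exact adjusted p = 0.0191), and 5' UTRs outside promoters held 0.279% and 0.310% (0.900, adjusted p = 1). Promoters were assigned first, so the larger promoter share of peaks lowers their shares in the other classes. Outside promoters, intergenic and intron summits numbered 515 and 283 among peaks, and 4679 and 4514 among background regions. Shares among regions outside promoters were not tested. Against the next-ranked regions the odds ratios were 0.647 for coding exons (exact adjusted p = 0.110), 1.30 for noncoding exons (adjusted p = 0.268), 0.897 for intergenic sequence (adjusted p = 0.202) and 0.713 for 5' UTRs (adjusted p = 0.774), none of them past the threshold. Promoters (1.501), introns (0.688) and 3' UTRs (0.538, exact adjusted p = 0.00956) passed it. The 3' UTR difference did not pass it with replicate 1's own top regions, of which 57 lay in 3' UTRs against 35 of the peaks (odds ratio 0.750, exact adjusted p = 0.0502), nor the intergenic one with the 897 highest peaks (0.906, adjusted p = 0.211).

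**Figure D2:**
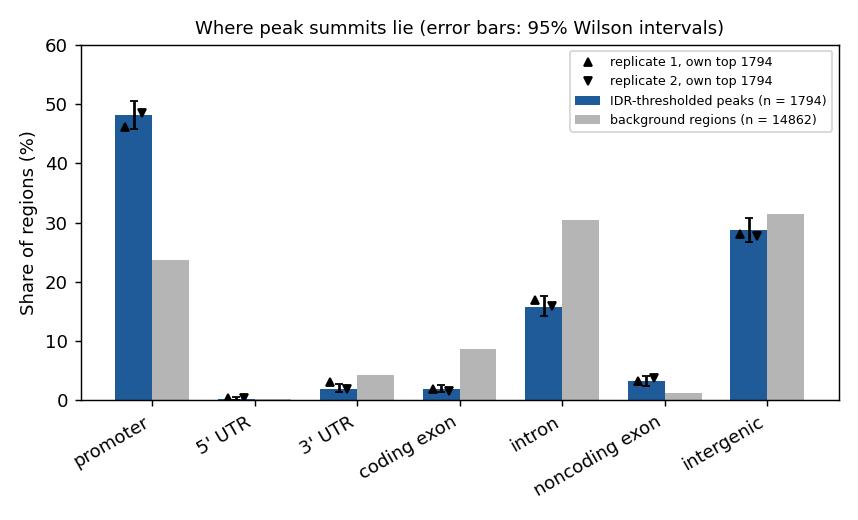
Share of summits in each annotation class (vertical, percent) for the 1794 peaks (blue, error bars 95% Wilson intervals) and 14862 background regions (grey), with triangles for each replicate's own 1794 highest regions. Promoters held 48.2% of peaks against 23.7% of background, and introns 15.8% against 30.4%.

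Chromosome III held 19.6% of peaks and 14.8% of background regions (odds ratio 1.41, 1.24 to 1.60, exact adjusted p = 4.45e-07), and the peaks at rpl-3, ufbp-1, tasp-1 and rpl-35 were among them. Chromosomes II (odds ratio 1.25, exact adjusted p = 0.00228) and I (1.18, adjusted p = 0.0204) also held more of the peaks than of the background. Chromosomes IV (0.687, exact adjusted p = 3.05e-07) and V (0.745, adjusted p = 4.71e-05) held less. The X held 19.1% of peaks and 19.7% of background (0.961, 0.848 to 1.09, exact adjusted p = 0.550). Against the next-ranked regions none of the 6 chromosomes passed the threshold (lowest adjusted p = 0.144 by Fisher's exact test; IV alone had an unadjusted p under 0.05, at 0.0239), and I also did not pass with replicate 1's own top regions (odds ratio 1.07, adjusted p = 0.369) and with peaks in the top of both replicates (1.18, adjusted p = 0.0559).

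Genes for cytosolic ribosomal proteins had the highest odds ratio of the 31 gene lists. A peak lay within 500 bp of a start site for 46 of the 68 with any region nearby (67.6%, Wilson interval 55.8 to 77.6%), against 14.7% of other protein-coding genes (odds ratio 12.1, 7.26 to 20.2, exact adjusted p = 4.50e-21). Within strata of GC content measured within 50 bp of the summit, a test chosen later, the odds ratio was 5.30 (3.01 to 9.36). The highest were rpl-3 (signal 843), rpl-20 (630), rpl-15 (596) and rpl-35 (553). Of the 6779 protein-coding genes with a region nearby, out of 19973 annotated, 1033 had a peak. Peaks were the highest regions of the same list, so the main odds ratios leave out differences between lists in having any region. A region lay near 68 of 79 annotated ribosomal protein genes, against 154 of 1310 chemosensory receptor genes. Each replicate's own top regions gave 45 of 68 ribosomal protein genes in replicate 1 and 44 of 68 in replicate 2.

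Genes of oxidative phosphorylation had peaks at 17 of 36 (odds ratio 5.04, exact adjusted p = 2.83e-05), led by cox-5A (377), cox-5B (244), cox-6B (222) and atp-1 (216), which encodes an ATP synthase subunit. With replicate 1's own top regions the count was 13 of 37 (3.33, exact adjusted p = 0.00561). Heat shock protein and chaperone genes had peaks at 20 of 45 (4.52, exact adjusted p = 1.65e-05), with hsp-110 (305), the chaperonin gene cct-1 (281), hsp-90 (279) and cct-8 (232) highest. Spliceosome and SR protein genes had peaks at 9 of 25 (3.15, exact adjusted p = 0.0270), including rsp-6 (146), snr-4 (138), prp-8 (121) and rsp-2 (111). The cell cycle list had peaks at 9 of 22 (3.88, exact adjusted p = 0.0112), with cdc-48.1 (688), cdk-5 (148), pcn-1 (121), the gene for the sliding clamp of DNA replication, and cdc-14 (101) highest. That list was drawn by symbol, and cdc-48.1, cdk-5, cdk-7 and cdk-9 among its 9 genes are also known for protein quality control, neuronal or transcriptional roles. The cell cycle odds ratio did not pass with the 897 highest peaks (3.29, exact adjusted p = 0.119), at 250 bp (3.25, adjusted p = 0.132), with peaks in the top of both replicates (2.62, adjusted p = 0.184) and with replicate 1's own top regions (2.29, adjusted p = 0.238). That of the spliceosome list did not pass with the 897 highest peaks (2.79, exact adjusted p = 0.142) and at 250 bp (1.80, adjusted p = 0.544).

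Peaks were less frequent near chemosensory receptor genes, at 5 of 154 (3.25% against 15.5%, odds ratio 0.183, 0.0748 to 0.447, exact adjusted p = 1.60e-05). Of these, srh-2 (157), srh-16 (92.3), srbc-58 (77.3) and sri-5 (67.2) had the highest signals, and srbc-58 and sri-5 were not in the top of both replicates. None of 41 neuropeptide genes had a peak (Wilson upper limit 8.57%, against 15.3% of other genes, Fisher's exact adjusted p = 0.00679). Each replicate's own top regions gave 1 of 41. The count was also 0 of 41 with the 897 highest peaks (exact adjusted p = 0.142) and with peaks in the top of both replicates (adjusted p = 0.0650), and 0 of 28 at 250 bp (adjusted p = 0.0920), but the list did not pass there, nor with replicate 1's own top regions (adjusted p = 0.0766).

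Among biotype lists, snoRNA genes, whose products guide modification of other RNAs, had peaks at 65 of 201 (32.3% against 10.3%, odds ratio 4.16, 3.08 to 5.61, exact adjusted p = 5.74e-16). F54E7.10 (277), W06H8.17 (271), Y53F4B.47 (215) and M7.15 (170) were highest. Genes annotated as snRNA had peaks at 15 of 44 (4.40, exact adjusted p = 0.000114), led by the SL2 spliced leader genes sls-2.2 (408), sls-2.4 (399) and sls-2.1 (383) and by R07E5.16 (208). Without piRNA genes in the reference set the snoRNA and snRNA lists had odds ratios of 2.74 and 2.91. With only regions over 500 bp from protein-coding start sites these were 6.79 and 9.47. There 26.95% of snoRNA and 35.1% of snRNA genes had a peak, against 32.3% and 34.1% in the main setting. The shares of other genes were 5.16% and 5.41%, against 10.3% and 10.5%. The higher odds ratios thus went mainly with lower shares of other genes. These settings were not combined. Transfer RNA genes had peaks at 66 of 337 (19.6% against 10.4%, 2.10, exact adjusted p = 6.72e-06). The highest were a gene at X:8036685-8036757 (signal 321), another at X:14063946-14064018 (188) and a pair at X:5801211-5801282 and X:5801472-5801543 that shared a peak (160). The transfer RNA odds ratio was 0.999 with the 897 highest peaks (exact adjusted p = 1), 1.40 with peaks in the top of both replicates (adjusted p = 0.198), 1.38 without piRNA genes and 4.35 with only regions over 500 bp from protein-coding start sites. In that last setting 18.8% of transfer RNA genes had a peak against 5.06% of others, so the share of other genes changed and not that of transfer RNA genes.

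The other 21 lists did not pass. Proteasome subunits had peaks at 7 of 21 (odds ratio 2.79, exact adjusted p = 0.0797) and translation factors at 9 of 33 (2.10, adjusted p = 0.161). Translation factors passed with the 897 highest peaks (4.22, exact adjusted p = 0.00472), and proteasome subunits at 250 bp (4.11, adjusted p = 0.0279). With all annotated genes as the reference set, translation factors (5.19, exact adjusted p = 0.000689), proteasome subunits (4.96, adjusted p = 0.00303) and vacuolar ATPase (6.14, adjusted p = 0.00612) passed with more peaks. That set includes genes with no region nearby, which cannot hold a peak. On that set cuticle collagens (exact adjusted p = 0.00371), moulting (0.0192), intestine (0.0129) and F-box genes (4.68e-05) passed with fewer, and the odds ratio of ribosomal proteins was 26.7, of oxidative phosphorylation 11.7 and of chemosensory receptors 0.0657. Moulting genes had peaks at 0 of 27 (exact adjusted p = 0.0746), cuticle collagens at 1 of 32 (0.161), homeobox genes at 1 of 31 (0.161) and genes of the intestine at 0 of 14 (0.270). The Wilson upper limits on the counts of 0 were 12.5% for moulting, 21.5% for the intestine and 65.8% for major sperm proteins. Vacuolar ATPase genes had peaks at 5 of 16, histones at 5 of 18, nuclear hormone receptors at 16 of 108, muscle genes at 4 of 34, germline and meiosis genes at 2 of 20, synapse genes at 1 of 22, aminoacyl tRNA synthetases at 2 of 23, F-box genes at 2 of 32 and miRNA genes at 11 (10.5% of those with a region, odds ratio 0.988). With replicate 2's own top regions 18 of 106 miRNA genes had a peak (odds ratio 1.71), and with replicate 1's 15.2% (1.64), neither past the threshold. Of the nuclear hormone receptors 10 of 108 had a peak with replicate 1's own top regions. The remaining counts were 4 of 15 for zinc finger genes, 3 of 11 for T-box and bHLH genes, 1 of 6 for heterochronic genes, 1 of 11 for Wnt and Notch signalling, 1 of 4 for dosage compensation and 0 of 2 for major sperm proteins. With a single replicate's own top regions several of these small lists moved by over 1.5 times without passing. Heterochronic genes were 2 of 6 in both replicates, and T-box and bHLH genes 1 of 11 in replicate 2 and 2 of 11 in replicate 1. In replicate 1 synapse genes were 2 of 22, germline and meiosis genes 1 of 20 and cuticle collagens 2 of 33, and the odds ratios of Wnt and Notch signalling (0.264 against 0.556) and dosage compensation (0.675 against 1.85) were lower.

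**Figure D3:**
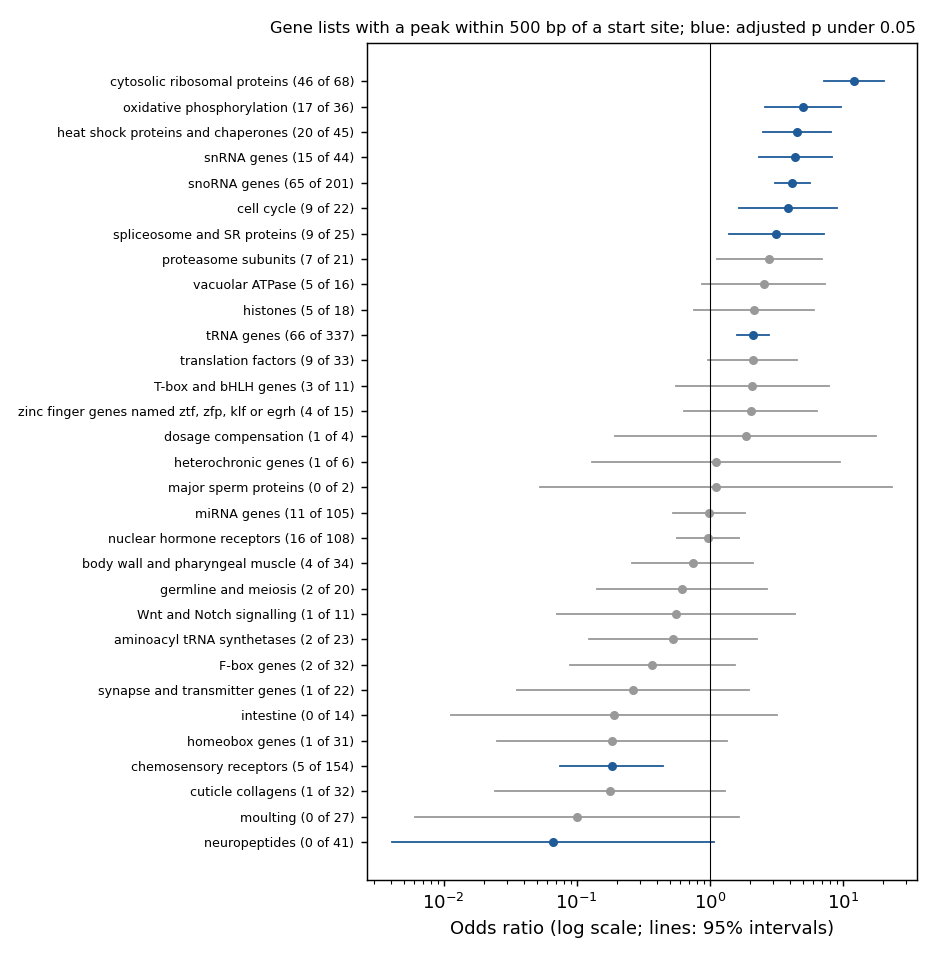
Odds ratio of a peak within 500 bp of a start site for each of the 31 gene lists (horizontal, log scale, points with 95% interval lines), with the number of members with a peak and with any region in brackets. Blue marks adjusted p under 0.05. Cytosolic ribosomal proteins stand highest at 12.1, and neuropeptides lowest with 0 of 41.

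Sequences at peak summits were richer in G and C than background (44.96% against 32.6% within 50 bp) and held purine-rich words with GAGA repeats. On chromosomes II, IV and X, GAGAGA lay in 25.3% of 886 peaks and 6.01% of 7793 background regions (odds ratio 5.30, 4.43 to 6.33, exact adjusted p = 1.43e-61). AGAGAG (odds ratio 5.41), ACGCAG (8.71), CGTCTC (7.25) and GACGCA (8.23) followed. Words of A and T were less frequent, with AAAATT in 18.1% of peaks and 49.3% of background (0.226), AAAAAT at 0.254 and TTAAAA at 0.201. Of 2080 words, 1076 differed in the search, and in the retest 586 were more and 323 less frequent in peaks. With background matched on GC content, 66 were more and 43 less frequent. The 5 leading words then had odds ratios from 2.07 to 2.62, and GAGCGC, chosen after its values were seen, had 4.42 (2.64 to 7.39, 9.08% against 2.21%, exact adjusted p = 4.27e-08). Against the next-ranked regions 53 words were more and 42 less frequent, and AGAGAG was no longer among them (1.26, exact adjusted p = 0.101). The odds ratios of the other leading words were then 1.36 for GAGAGA, 2.14 for ACGCAG, 1.82 for CGTCTC and 1.95 for GACGCA.

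No region of the pooled list or of either replicate overlapped the endogenous ztf-4 locus (I:6926257-6929665). The unc-119 locus (III:10902641-10908935) overlapped 6 regions of the pooled list, 6 of replicate 1 and 7 of replicate 2, none of them a peak. The best of these ranked 4822 in the pooled list with a signal of 37.7. Both loci are represented in the transgene, and the regions were called against a control.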

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

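Of the alternatives named here, peaks within 1000 bp counted once, GC-matched background for start sites, biotype lists without piRNA genes or away from protein-coding start sites, and GC content within 50 bp were chosen after the data were seen. The number of peaks was 897 with only those of highest signal and 1138 with those in the top of both replicates, both fewer by construction. With the next-ranked regions as background, 3 of 7 annotation classes, 0 of 6 chromosomes and 53 words (more frequent in peaks) passed, against 6, 5 and 586, and GC-matched background gave 66 words. These 2 backgrounds held fewer regions, which lowers power, and the odds ratios of the leading words were also nearer 1. In the pooled list 3361 regions had a q-value under the threshold used for adjusted p, among them all 1794 peaks. Regions ranked directly below the peaks can therefore be enriched themselves, and that setting may compare stronger with weaker enriched regions. How many of these regions passed was not counted, and the cause of the smaller counts was not tested. With all annotated genes as the reference set 17 lists passed, against 10. That set includes genes with no region nearby, which cannot hold a peak, so its odds ratios also measure having a region. How far this accounts for the added lists was not tested. Odds ratios that moved to the other side of 1, none past the threshold there and the cause not tested, were transfer RNA 0.999 and miRNA 1.77 with the 897 highest peaks; miRNA 1.40, dosage compensation 0.982 and T-box and bHLH genes 0.885 with peaks in the top of both replicates; zinc finger genes 0.727 at 250 bp; miRNA 1.57, germline 1.06 and major sperm proteins 0.372 at 1000 bp. With all genes these were miRNA 1.18, aminoacyl tRNA synthetases 1.22, nuclear hormone receptors 1.14, muscle 1.44 and major sperm proteins 0.290, and away from protein-coding start sites miRNA 1.38. Without a replicate they were miRNA 1.64 to 1.71, and they ranged for T-box and bHLH genes from 0.554 (without replicate 1) to 1.35, for dosage compensation from 0.675 (without replicate 2) to 1.85 and for muscle from 0.738 to 1.05 (without replicate 2). In 37 other comparisons of a main result with an alternative the direction and the side of the threshold held, or for counts the value stayed within 1.5 times, including start sites under all 8 alternatives run (odds ratios 1.501 to 3.28) and the replicate overlap (at least 58.0% shared). Among single classes, chromosomes, lists and words, 262 comparisons kept direction and side of the threshold, 24 lost their call, 9 gained one and the 20 just given changed direction. No paired analysis was possible because there is a single group. Depth could not be weighed, since the files hold no counts.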

Other observations

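The groups and distal peaks named here, the tests on distal peaks, both tests of GC content near ribosomal protein genes and the GC-matched background for start sites were chosen after the data were seen.

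Of 17 SL2 spliced leader RNA genes with a region within 500 bp (18 annotated), 5 had a peak (29.4%, Wilson interval 13.3 to 53.1%), and those at sls-2.2, sls-2.4 and sls-2.1 ranked 9, 10 and 13 among all peaks. The whole snRNA list, which includes SL2 genes, had a share of 34.1%, against 10.5% of genes outside it, or 15.1% without piRNA genes. The last of these lies within the SL2 interval, and SL2 genes were not tested separately. SL2 RNA supplies the leader that is spliced onto downstream genes of operons. The peak at sls-2.8 ranked 193 and that at sls-2.9 1778. None of the 12 annotated SL1 RNA genes and none of 20 rRNA genes had a region of the pooled list within 500 bp. That list is mostly background, so without any region these loci could not be assessed. Whether the tagged protein was there remains unknown. Of 5336 piRNA genes with a region, 78 had a peak (1.46%, Wilson interval 1.17 to 1.82%), against 11 of 62 lincRNA genes (17.7%, 10.2 to 29.0%) and 12 of 174 pseudogenes (6.90%, 3.99 to 11.7%). The difference between these groups was not tested.

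Far from start sites, 659 peaks (36.7%) lay over 1000 bp from any protein-coding start site, among them 36 of the highest 100. The highest was at IV:3644800-3645448 (signal 479, rank 8), 24 bp outside the gene CC8.2. Another lay at X:4209177-4209398 (392, rank 11), 1294 bp outside hpk-1, and was 56.4% G and C within 50 bp of its summit. The peak ranked 8 was 30.7% G and C in that window. The peak ranked 26 lay in an intron of epg-9 at IV:2602062-2602262 (317) and held 4 of the 5 leading words. Distal peaks ranked 17 and 22 held 3 and 1 of them, and those ranked 8, 9, 11, 12 and 25 held 0. Repeated sequence is a candidate explanation for the distal peaks. It is argued against as the whole cause, since 19.1% of their summits lay in masked repeats against 43.4% of equally distant background regions (odds ratio 0.309, 0.253 to 0.377). The leading words lay in 45.5% of distal and 46.5% of promoter peaks (odds ratio 0.960, 0.784 to 1.18), which leaves open whether the words mark either kind more. Distance was taken to protein-coding start sites only, and some of these peaks lay near RNA genes. The peak ranked 9 was 171 bp from the start site of sls-2.2, and that ranked 25 was 313 bp from that of a transfer RNA gene. Enhancers and unannotated promoters were not tested.

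Strong transcription may draw ChIP signal whatever the protein, which would raise the ribosomal protein, transfer RNA and translation factor lists together. As reported, 2 of these 3 lists passed, and the interval of the translation factors (0.971 to 4.52) leaves the explanation open. With all annotated genes as the reference set all 3 passed (translation factors 5.19), as the explanation needs. Genes with no region nearby cannot hold a peak, so on that set an odds ratio also measures having a region. A region lay near 33 of 41 translation factor genes, against 6779 of 19973 protein-coding genes. With the 897 highest peaks the odds ratio of transfer RNA genes was 0.999, so the explanation stays open. GC content near the genes could also raise the ribosomal protein list. Within 10 strata of GC content, measured within 250 bp of each summit, the odds ratio was 11.6 (6.89 to 19.5). Median GC content hardly differed in that window (34.4% against 34.3%), so it could say little about this explanation. Measured within 50 bp, where ribosomal protein regions had a median GC content of 48.0% against 35.6%, the odds ratio was 5.30 (3.01 to 9.36). GC content within 50 bp is thus argued against as the whole cause, but part of the difference could go with it. An untagged strain was not analysed here, the design has 1 group, and no biological explanation was tested.

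GC content could also place peaks near start sites. With background matched on GC content the odds ratio was 2.32 (2.01 to 2.68) against 2.99 unmatched, so GC content within 50 bp is argued against as the whole cause.

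The window around ztf-4 held 1 region of the pooled list, against a median of 9 in equal windows around other protein-coding genes (percentile 9.25). The window around unc-119 held 6 regions against a median of 4 (percentile 68.6). Regions were called against a control whose strain is not given, so neither window measures the number of transgene copies.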
